A study of Mus musculus with 10 samples.

How the data were processed

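RNA of 10 mouse colon organoid libraries, 5 treated with vehicle and 5 with WY-14643, was analysed from 1 table of 56748 genes with a column per library. The deposited values are FPKM, fragments scaled by gene length and by a factor per library, made by the authors. Per the submitters' processing notes HISAT2 2.0.5, featureCounts 1.5.0-p3 and build mm39 were used. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Per the labels' protocols, messenger RNA was captured on poly-T beads and fragmented, and complementary DNA was primed with random hexamers; the protocol covers both unstranded and stranded libraries without saying which was made, so reads of overlapping or antisense genes cannot be told apart. Coordinates are those of the table.

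Multiplying FPKM by gene length and dividing by the smallest such value of the library gave whole numbers in 100% of the values above 0 of every library (tolerance 0.01), so the reads behind each value were recovered, 15618244 to 29271304 per library. FPKM multiplied by gene length in kilobases summed to 959082.5 to 1043426 per library, and the median ratio of each library to the geometric mean over genes was 1.01 in all 10, so scaling by that ratio moves nothing. No source used here says how the libraries were scaled, but the same median ratio in all 10 argues against scaling by total reads alone. Counts of reads were used for depth, for a voom alternative and for checks only. Mitochondrial genes took 0.792% to 2.58% of the reads and rRNA genes 0.633% to 1.72%.

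Samples were grouped by the treatment in the labels, and replicates 1 to 5 and 6 to 10 are the numbers in the library names. No pair of libraries held the same values: over abundant genes, chi-square per degree of freedom of the recovered reads was 14.8 to 39.4 for the matched libraries described below and 77.5 to 282 for all others. Genes with a mean FPKM of at least 0.5 over all 10 libraries were tested, 13607 or 24% of the table. WY-14643 was compared with vehicle by limma 3.58.1 in R 4.3.3 (linear model on log2(FPKM + 1), eBayes with a mean-variance trend and robust priors, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The pseudocount was 1.

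A total of 35 gene lists were fixed before the data were examined, and the 29 with at least 3 tested members were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists. With an estimated correlation 2 of the 13 calls held, those of PPARα targets and mitochondrial β-oxidation, and fry, which tests whether a set's genes move on balance in one direction, passed the same 2. The sets were also tested in the matched fit. The mean level of each list per library was also tested by an exact two-sided permutation test. Lists overlap: PPARα targets share 5 members with mitochondrial β-oxidation and 6 with peroxisomal oxidation.

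Genes were named by a rule fixed before the data were examined: the receptors Ppara, Ppard and Pparg; up to 12 protein-coding genes per direction with the largest change among those that passed, with a mean FPKM of at least 1 in the higher group and no overlap between groups; up to 4 members with the smallest p in each list and up to 2 that a reader would look for; and the most abundant members of the lists of other cell types. The second part named 0 genes in the planned fit. Applied to the matched fit described next, it found 15 genes higher, of which 12 were named, and 0 lower. Some genes of the rule are not reported here, and other genes called by the matched fit were chosen for the text after their values were seen.

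Replicate numbers are not shared between groups in the labels, so the planned fit has no pairs. Deviations from the group means showed that vehicle replicate 1 goes with WY-14643 replicate 6 and so on (correlations 0.423 to 0.782 across genes, at most 0.0602 for unmatched libraries of different groups). A matched fit, with pair as a block, was decided on from these correlations before its calls were computed, and its own alternatives were added after. The pairing comes from the data and the numerical order, not from a label.

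The fits were tested on simulated data: reads for the 13607 genes with 200 changed, drawn with the differences between pairs kept. The fit without pairs recovered 12% of 1.5-fold and 48% of 2-fold changes, with 0 false among 60 calls, and the matched fit 86% and 98%, with 14 false among 198 calls. With the differences between pairs removed the fit without pairs recovered 91% and 99%. The simulation gave every gene the same dispersion, the median estimated within the matched pairs (0.0051), so genes with a larger spread are not covered by these shares. The 200 changed genes were drawn only from genes above a minimum of expected reads, so genes with few reads are not covered either.

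Alternatives were other pseudocounts (0.1 and 0.5), no filter or a mean FPKM of at least 2, TPM, quantile normalization, limma without trend or robust priors, voom on recovered reads, library weights, protein-coding genes only and leaving out each library. Depth limits the precision of low genes, and statements of counting error cover reads, not molecules.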

Results

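Mouse colon organoids, cultures of intestinal epithelium that grow from crypt cells, received WY-14643 or its vehicle for 2 days, beginning 3 days after they were passaged. WY-14643 is a synthetic agonist of PPARα, a nuclear receptor that binds fatty acids and turns on genes of their oxidation, and it was given at 100 µM. Polyadenylated RNA was sequenced from 5 vehicle libraries (replicates 1 to 5) and 5 WY-14643 libraries (replicates 6 to 10). Between 15618244 and 29271304 gene-assigned reads stood behind each library, with a mean of 20767442 ± 5187374 reads for vehicle and 17813562 ± 2520570 reads for WY-14643 (SD, n = 5 each). The single comparison of the design asks how WY-14643 changes gene expression in colon epithelium. The title of the series ties microbial nicotinic acid to colon regional identity and to injury. In no group was PPARα removed or blocked, so changes cannot be assigned to that receptor. The labels name no animal, organoid line or day for the replicates, so p-values measure the spread between these libraries, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values, and adjusted p-values of genes come from limma over 13607 genes without pairs unless a list, another fit or the matched fit is named.

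Genes of fatty acid oxidation stood higher after WY-14643. All 22 tested members of the list of PPARα target genes had a higher mean, with a median log2 fold change of 0.60, and the list rose as a set (camera, adjusted p = 2.20e-39 with a preset correlation and adjusted p = 0.00948 with an estimated correlation). It did not pass in the matched fit described below with an estimated correlation (adjusted p = 0.101). The list held 35 genes, and those below the filter on mean FPKM were not tested. Among them Cyp4a10, Cyp4a14 and Cyp4a31 were at 0 FPKM in both groups. The low means of others went either way, as for Acot4 (0.143 and 0.248 FPKM in vehicle and WY-14643) and Fgf21 (0.122 and 0.0850 FPKM). Cpt1a, which makes the acylcarnitines that carry long-chain fatty acids into mitochondria, was at 11.5 ± 2.39 FPKM in vehicle and 26.6 ± 3.52 FPKM in WY-14643 libraries (SD, n = 5 each). Acadl, a long-chain acyl-CoA dehydrogenase, went from 61.3 ± 6.69 to 96.4 ± 10.9 FPKM, and Cpt2, the inner-membrane partner of Cpt1a, from 14.0 ± 1.53 to 21.8 ± 3.76 FPKM. Each of these 3 genes passed when adjusted over the list alone (limma, adjusted p = 1.48e-04 for Cpt1a, 9.88e-04 for Acadl and 0.00457 for Cpt2), while none passed over all genes, where Cpt1a had the smallest adjusted p of 0.0917. Fabp1, the liver-type fatty acid-binding protein, averaged 0.0125 ± 0.0278 FPKM in vehicle and 3.53 ± 6.0 FPKM in WY-14643, and Angptl4, a secreted lipase inhibitor, averaged 0.227 ± 0.455 and 1.11 ± 1.57 FPKM. Neither passed over the list alone (limma, adjusted p = 0.0572 and 0.218), but both did so in the matched fit (adjusted p = 0.0384 and 0.0180). Fabp1 and Angptl4 reached the filter only through the higher mean of their WY-14643 libraries.

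**Figure D1:**
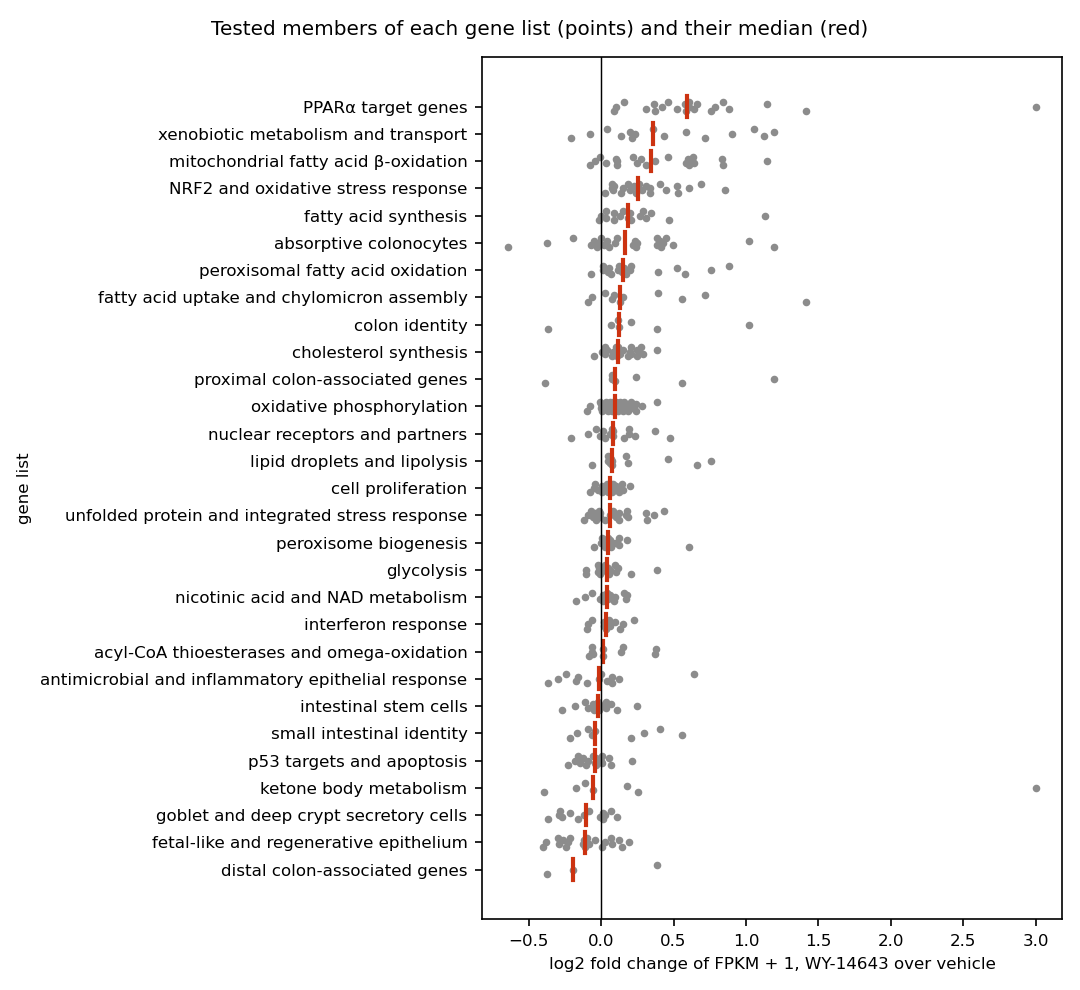
Each grey point is a tested gene of the list named on the vertical axis, placed by its log2 fold change of FPKM + 1 (WY-14643 over vehicle, n = 5 each), and the red bar is the list's median. The 22 tested PPARα target genes all lie above 0, with a median of 0.60.

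Of the 22 tested PPARα targets, 0 passed over all genes tested and 12 rose when adjusted over the list alone (8 and 20 in the matched fit). The count of 12 fell to 5 without vehicle replicate 1 or without WY-14643 replicate 7, to 6 without WY-14643 replicate 8 and to 7 without vehicle replicate 4. The mean log2 level over the list was 2.83 in vehicle and 3.53 in WY-14643 libraries, and every WY-14643 library of a matched pair stood above its vehicle partner, by 0.77, 0.78, 0.71, 0.88 and 0.33 in pairs 1 to 5. In an exact two-sided permutation test of these library means the p was 0.00794, the smallest that 5 against 5 libraries can give, and 0.230 after Benjamini-Hochberg adjustment over 29 lists. At this floor no list on its own can pass the adjustment, so the 0.230 decides nothing. The permutation test also leaves out the pairing.

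The enzymes of mitochondrial β-oxidation also rose as a set, with a median log2 fold change of 0.34 over 22 members (camera, adjusted p = 5.61e-35 with a preset correlation and adjusted p = 0.0142 with an estimated correlation). They did not pass in the matched fit with an estimated correlation (adjusted p = 0.101). In the exact permutation test of library means the p was 0.0159, and 0.230 after an adjustment that no list on its own can pass. This list shares 5 members with that of PPARα targets. Of its 22 members, 0 passed over all genes and 13 rose when adjusted over the list alone (6 and 15 in the matched fit), or 8 without vehicle replicate 4 and 8 without WY-14643 replicate 8. Eci2, an isomerase needed for unsaturated fatty acids, went from 3.56 ± 0.204 to 5.94 ± 0.569 FPKM, and Hadha, a subunit of the trifunctional protein, from 20.5 ± 0.949 to 32 ± 5.0 FPKM, and both rose over the list alone (limma, adjusted p = 2.72e-04 and 8.01e-04). Acadm, the medium-chain dehydrogenase, was at 25.3 ± 6.87 and 26.8 ± 4.44 FPKM and did not pass.

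No gene was called by the test fixed before the data were examined: with limma on all 10 libraries, 0 genes were higher and 0 lower of 13607, and 205 had an unadjusted p under 0.05, where 680 would by chance; voom on the recovered reads also called 0, with 187 at an unadjusted p under 0.05. The count was 1 without vehicle replicate 2 (Cpt1a), 2 without vehicle replicate 5 (Akr1b8 and Sgk2) and 1 without WY-14643 replicate 10. In 33 genes every WY-14643 library lay above every vehicle library and in 15 genes below, against 54 expected by chance for each direction (0.397% of the genes). The 54 and the 680 take no account of the match of the libraries in pairs, and the 54 assumes 10 exchangeable libraries. The 33, 15, 205 and 187 therefore cannot be read as fewer than chance gives. Within the matched pairs, 766 genes were higher and 829 lower in 5 of 5, against 425 expected by chance for each direction. In the matched fit 1438 genes had an unadjusted p under 0.05, against 680 expected by chance. Genes vary together, so such counts can lie far from 425 and 680 by chance. Treatment was not exchanged within pairs for these counts. The 766, 829 and 1438 therefore cannot be read as more than chance gives. Giving each library a quality weight, an alternative also fixed beforehand, called 18 higher and 3 lower. It weighted vehicle replicate 3 by 4.35 and WY-14643 replicate 8 by 3.90, and every other library by 0.552 to 1.025.

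The low count went with large differences between libraries of one group. Vehicle replicate 1 deviated from its group mean in the same genes as WY-14643 replicate 6, replicate 2 as replicate 7, and so on in numerical order, with correlations across genes of 0.423 to 0.782, whereas the highest correlation between unmatched libraries of the 2 groups was 0.0602. Genes are not independent replicates, so the order was tested over libraries: of the 120 ways to assign the libraries, the numbered one had the highest mean correlation, 0.653 (exact permutation test, one-sided, p = 0.00833, the smallest possible). The labels state no pairing. A fit with these pairs as a block was added after the data were examined, and its calls are given here as those of the matched fit.

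**Figure D2:**
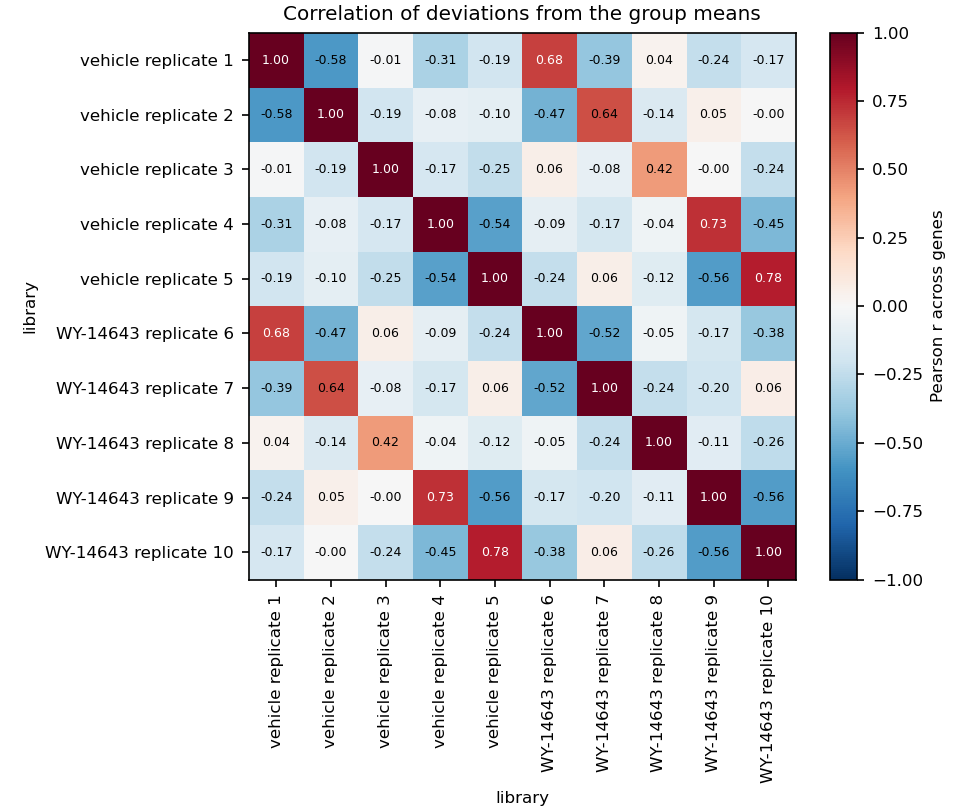
Pearson correlations, across 13607 genes, of each library's deviations from its own group mean, for the 10 libraries on both axes. Vehicle replicates 1 to 5 correlate with WY-14643 replicates 6 to 10 in numerical order, at 0.423 to 0.782, and with no other WY-14643 library above 0.0602.

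In the matched fit 39 genes were higher and 4 lower (limma, 5 pairs), 6 of them at least 2-fold higher and 1 at least 2-fold lower. The 39 held 35 protein-coding genes, 3 pseudogenes and 1 microRNA gene. Without the pair of replicates 2 and 7, 3 genes were higher and 0 lower (Akr1b8, Cpt1a and Abhd6), without replicates 3 and 8, 2 higher and 0 lower (Akr1b8 and Abhd6), and without replicates 4 and 9, 12 higher and 1 lower. With no filter on low values, 2 were higher (Akr1b8 and Abhd6) and 0 lower.

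The fixed rule for named genes, applied to the matched fit, took 12 higher genes, of which Cpt1a, Acadl and Acaa2 belong to fatty acid oxidation. Akr1b8, an aldo-keto reductase, rose from 83.1 ± 16.8 to 174 ± 22.4 FPKM, a log2 fold change of 1.07 ± 0.05 (matched SE, adjusted p = 0.00241; 0.112 without pairs), and Cpt1a by a log2 fold change of 1.15 ± 0.08 (adjusted p = 0.010; 0.0917 without pairs). Abhd6, a monoacylglycerol lipase, rose from 13 ± 3.04 to 24.5 ± 5.69 FPKM (matched adjusted p = 0.00241). Acaa2, the mitochondrial thiolase, rose from 51.9 ± 11.1 to 93.3 ± 18.7 FPKM (matched adjusted p = 0.0202). Fbp2, a fructose-1,6-bisphosphatase of gluconeogenesis, rose from 75.7 ± 11.8 to 126.2 ± 10.6 FPKM, and Aldh9a1, an aldehyde dehydrogenase of carnitine synthesis, from 20.9 ± 3.88 to 34.0 ± 6.24 FPKM. Acacb, an acetyl-CoA carboxylase isoform whose product inhibits carnitine palmitoyltransferase, rose from 0.143 ± 0.0988 to 1.59 ± 0.797 FPKM. Hsdl2 rose by a log2 fold change of 0.86, the kinase gene Sgk2 by 0.98, the transcription factor gene Klf11 by 0.78 and the phosphatase gene Ppef1 by 1.18. The rule requires no overlap between groups and a matched adjusted p under 0.05. By that selection each of these 12 genes is higher in 5 of 5 pairs, so this gives no further support. Their matched adjusted p lay between 0.00241 and 0.0481. None passed in the planned fit. Library weights, also without pairs, called 10 of the 12, all but Abhd6 and Aldh9a1 (adjusted p between 0.00404 and 0.0343). The genes were chosen from the same libraries for no overlap between groups, so these calls give no independent support. That fit also leans on 1 matched pair, vehicle replicate 3 and WY-14643 replicate 8.

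The genes lie on these stretches of the mouse genome in build mm39, as the gene table gives them: Cpt1a on chromosome 19 from 3372334 to 3435733 (ENSMUSG00000024900), Akr1b8 on chromosome 6 from 34331054 to 34345398 (ENSMUSG00000029762), Abhd6 on chromosome 14 from 14413010 to 14466871 (ENSMUSG00000025277), Acadl on chromosome 1 from 66869998 to 66902436 (ENSMUSG00000026003), Acaa2 on chromosome 18 from 74912268 to 74939279 (ENSMUSG00000036880) and Fbp2 on chromosome 13 from 62984691 to 63006236 (ENSMUSG00000021456). These are whole-gene spans, and values are summed over exons of a gene.

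**Figure D3:**
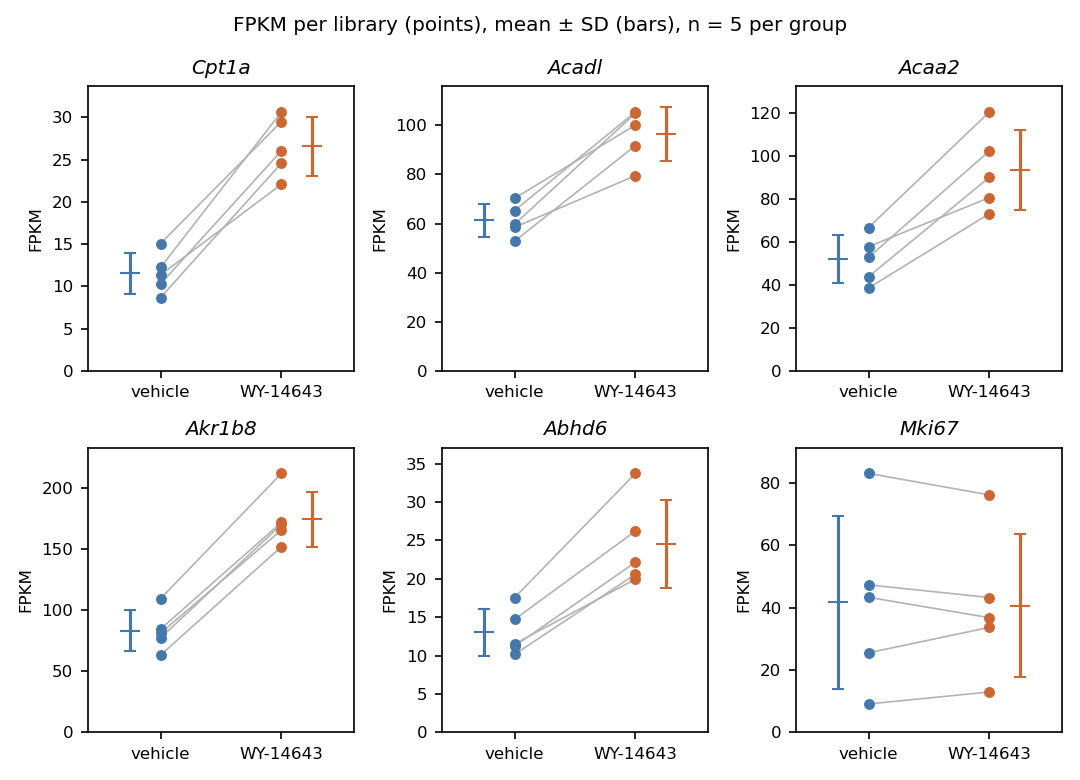
FPKM of 6 genes in each library (points; blue vehicle, orange WY-14643), with grey lines joining vehicle replicates 1 to 5 to WY-14643 replicates 6 to 10 in order, and mean ± SD of 5 libraries beside the points. In Cpt1a, Acadl, Acaa2, Akr1b8 and Abhd6 every WY-14643 library lies above every vehicle library, which the rule that named them requires. Mki67, not named by that rule, ranges from 9.12 to 83.0 FPKM in vehicle libraries and the groups overlap.

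Among genes outside the 12, the matched fit also called Slc25a20, the mitochondrial carnitine-acylcarnitine carrier, at 9.12 ± 4.11 and 16.8 ± 6.12 FPKM (matched adjusted p = 0.010), Ech1 at 44.1 ± 13 and 74.4 ± 17.7 FPKM and Eci2. Pex11a, which takes part in peroxisome division, and Ehhadh, the peroxisomal bifunctional enzyme, were called with log2 fold changes of 0.60 and 0.58, as were Idh1 with 0.48 and Nr1i2, the xenobiotic receptor PXR, with 0.47. The largest fold change of a called gene was that of 1810065E05Rik, at 16.1 ± 18.7 FPKM in vehicle and 80.9 ± 87.2 FPKM in WY-14643 (log2 2.14). The 4 lower calls were Nat8l, at 8.25 ± 4.03 and 5.85 ± 2.94 FPKM, the pseudogene Gm44223, a U4 small nuclear RNA gene and a 5S rRNA gene. The last 2 rest on means of 5.6 and 2.6 reads per vehicle library, and the microRNA gene Mir130b, among the higher calls, on 2.2 reads per WY-14643 library. Hadhb-ps, a processed pseudogene of Hadhb, was called with a log2 fold change of 0.61, and reads of these near-identical sequences may be shared, so its change is uncertain.

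The peroxisomal oxidation enzymes were higher as a set (18 members, median log2 fold change 0.15; camera, adjusted p = 5.84e-11), but not beyond chance once the correlation was estimated (adjusted p = 0.0943 with an estimated correlation). Over the list alone 1 member rose, Acaa1b, from 0.524 ± 0.264 to 1.91 ± 0.958 FPKM, and 0 over all genes. The matched fit called 2 over all genes and 6 over the list alone. The list's symbol Peci, an older name of Eci2, matched no gene name in the data, so Eci2 is not in these counts. Under its current name Eci2 was tested in the list of mitochondrial β-oxidation, and the matched fit called it (limma, adjusted p = 0.0128). Peroxisome biogenesis, with a median of 0.05 over 16 members, passed camera (adjusted p = 0.00249), but not without vehicle replicate 1 (0.128), nor with an estimated correlation (adjusted p = 0.172). In fry with pairs peroxisomal oxidation and peroxisome biogenesis both passed (adjusted p = 0.00881 and 0.00721). In camera with pairs and an estimated correlation neither did (adjusted p = 0.109 and 0.147). Acyl-CoA thioesterases and ω-oxidation did not pass (10 members, adjusted p = 0.252), and Acot2 was at 0.997 ± 1.64 and 1.34 ± 1.19 FPKM. Ketone body metabolism did not pass (7 members, adjusted p = 0.0714); its median was -0.05 and its mean 0.39, and the test's direction was higher. Oxct1, which starts ketone use, had a log2 fold change of -0.39; in the matched fit it fell over that list alone and Slc16a1 rose.

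Lists of lipid handling were higher with the preset correlation and not with an estimated one. In fry with pairs, lipid droplets (adjusted p = 0.0188) and fatty acid synthesis (0.0430) passed. Fatty acid uptake (0.116) and cholesterol synthesis (0.0961) did not pass there. Lipid droplets and lipolysis had a median of 0.07 over 12 members (adjusted p = 0.00332; adjusted p = 0.162 with an estimated correlation), and the call was lost without vehicle replicate 1 (0.0589) or WY-14643 replicate 9 (0.102). Plin2, a lipid droplet coat protein, was at 29.5 ± 11.1 and 44.2 ± 24.7 FPKM and Hilpda at 31.1 ± 14.6 and 55.5 ± 33.7 FPKM. Fatty acid uptake and chylomicron assembly had a median of 0.13 over 11 members (adjusted p = 6.94e-04; adjusted p = 0.211 with an estimated correlation; 0.0707 without vehicle replicate 1). Fatty acid synthesis had a median of 0.18 over 17 members (adjusted p = 3.42e-05; adjusted p = 0.275 with an estimated correlation; 0.0943 without vehicle replicate 4). Acacb was its 1 member to rise over the list alone, and Fasn, the fatty acid synthase, was at 34.8 ± 9.14 and 38.8 ± 10.8 FPKM. Cholesterol synthesis had a median of 0.12 over 25 members (adjusted p = 2.02e-04; adjusted p = 0.514 with an estimated correlation), with no call without vehicle replicate 4 (0.271) or WY-14643 replicate 7 (0.169). Adjusted over the list alone, the matched fit called 3, 1, 9 and 7 members of these 4 lists higher.

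Oxidative stress and detoxification genes behaved likewise. In fry with pairs the NRF2 and xenobiotic lists passed (adjusted p = 0.00839 and 0.0430), and oxidative phosphorylation did not (0.0933). In camera with pairs and an estimated correlation the NRF2 and xenobiotic lists did not pass (adjusted p = 0.101 and 0.149). All 24 members of the NRF2 list had a higher mean, with a median of 0.26 (camera, adjusted p = 1.45e-11; adjusted p = 0.0635 with an estimated correlation), but 0 passed over all genes or over the list alone. Its members include Nqo1, a quinone reductase, at 32.3 ± 16.1 and 55.5 ± 24.0 FPKM, Hmox1, the haem oxygenase, at 17.7 ± 5.19 and 25.3 ± 4.16 FPKM, and Gstm1 at 22.8 ± 6.95 and 37.9 ± 13.9 FPKM. In the matched fit 14 of the 24 rose over the list alone. Xenobiotic metabolism and transport had a median of 0.36 over 15 members (adjusted p = 3.72e-07; adjusted p = 0.211 with an estimated correlation), 0 of which passed alone without pairs and 9 with pairs. Aldh1a1, which makes retinoic acid, was at 22.2 ± 10.5 and 45.5 ± 6.70 FPKM, and Cyp2c55, a colonic cytochrome P450, at 39.5 ± 47.8 and 81.9 ± 73.1 FPKM. Oxidative phosphorylation had a median of 0.09 over 48 members (adjusted p = 2.94e-08; adjusted p = 0.514 with an estimated correlation; 0.241 without vehicle replicate 4), and 0 members passed in either fit. Glycolysis did not pass (17 members, adjusted p = 0.463).

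Receptor transcripts did not pass the test. Ppara was at 0.298 ± 0.174 FPKM in vehicle and 0.336 ± 0.177 FPKM in WY-14643 libraries, on 9 to 63 reads per library, which is below the filter, so its values come from the fit without a filter (limma, adjusted p = 1.0). Ppard was at 14.0 ± 2.05 and 14.7 ± 1.79 FPKM and Pparg at 28.9 ± 16.7 and 22.9 ± 8.32 FPKM. Nuclear receptors and their partners did not pass as a list (16 members, adjusted p = 0.0670; 0.00501 in the matched fit, and adjusted p = 0.377 there with an estimated correlation). Genes of nicotinic acid and NAD metabolism did not pass (15 members, median 0.04, adjusted p = 0.346); Naprt, which turns nicotinic acid into its mononucleotide, was at 2.33 ± 0.969 and 2.63 ± 0.588 FPKM and Nampt, its nicotinamide counterpart, at 29.6 ± 9.61 and 30.2 ± 7.18 FPKM.

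Markers of cell state and of colon region showed no call that held under all alternatives. Intestinal stem cell genes did not pass (17 members, median -0.02, adjusted p = 0.474), with Lgr5 at 4.79 ± 0.852 and 3.79 ± 0.554 FPKM and Axin2 at 20 ± 6.25 and 19.1 ± 5.58 FPKM. Cell proliferation did not pass (30 members, median 0.06, adjusted p = 0.458), with Mki67 at 41.7 ± 27.7 and 40.6 ± 22.9 FPKM. It was called lower without vehicle replicate 4 (1.17e-06) and higher without WY-14643 replicate 9 (1.93e-06). Those replicates form the matched pair with the lowest proliferation level, and each of these fits keeps only its partner. Absorptive colonocyte genes had a median of 0.16 over 26 members (camera, adjusted p = 0.0406; adjusted p = 0.606 with an estimated correlation); Car1, a carbonic anhydrase of colonocytes, was at 360 ± 360 and 652 ± 613 FPKM and Krt20 at 65.3 ± 43.5 and 81.3 ± 59.7 FPKM. That call was lost without vehicle replicate 1 (0.534), 3 (0.0798) or 5 (0.989) and without WY-14643 replicate 7 (0.592) or 9 (0.678). Goblet and deep crypt secretory genes did not pass (14 members, median -0.10, adjusted p = 0.251), with Muc2 at 6.28 ± 3.33 and 4.60 ± 2.42 FPKM. Fetal-like and regenerative genes had a median of -0.11 over 22 members (adjusted p = 0.0499; adjusted p = 0.606 with an estimated correlation), with Clu at 476 ± 195 and 406 ± 190 FPKM and Ly6a at 640 ± 148 and 671 ± 143 FPKM. This call was lost without vehicle replicate 1 (0.981, with the direction turned) or 4 (0.0943) and without WY-14643 replicate 7 (0.707), 8 (0.103) or 10 (0.222). No member of these lists passed over all genes or over the list alone; in the matched fit, 5 absorptive genes rose and 4 fetal-like genes fell over the list alone (Anxa3, Ankrd1, Krt7 and Cd55).

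Proximal colon-associated genes (7 members, median 0.10, adjusted p = 0.0874) and colon identity genes (7 members, median 0.12, adjusted p = 0.0874) did not pass. In the matched fit camera called both higher (adjusted p = 0.0139 and 0.00620), with adjusted p = 0.166 and 0.245 with an estimated correlation. Fry with pairs passed the proximal genes (adjusted p = 0.0467) and not the colon identity genes (0.0829). Cyp2c55 is in the first list and Car1 in the second; Aqp4, a proximal water channel, was at 2.61 ± 2.50 and 1.5 ± 1.38 FPKM. Over the list of proximal genes alone, the matched fit called Cyp2c55 and Fabp2 higher and Aqp4 lower. Over the list of colon identity alone, the matched fit called Car1, Cdx1 and Slc26a3 higher and Muc2 lower. Distal colon-associated genes (3 members, median -0.19, adjusted p = 0.531) and small intestinal identity genes (9 members, median -0.04 and mean 0.10, tested direction higher, adjusted p = 0.474) did not pass; in the matched fit, adjusted over the list alone, Ly6g fell and Slc26a3 rose among the distal genes. Of the HOX genes of groups 9 to 13, 1 of 16 passed the filter, Hoxb9, at 52.5 ± 9.51 and 53.3 ± 9.24 FPKM.

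Inflammatory and stress lists did not pass: antimicrobial and inflammatory epithelial response (13 members, adjusted p = 0.465), interferon response (13 members, adjusted p = 0.444), p53 targets and apoptosis (17 members, adjusted p = 0.218) and unfolded protein and integrated stress response (23 members, adjusted p = 0.125; 0.0145 in the matched fit, and adjusted p = 0.245 there with an estimated correlation). Cdkn1a, a p53 target that halts the cell cycle, was at 83.3 ± 14.8 and 81.3 ± 15.4 FPKM. Of 18 immune genes 1 was tested, Cd68, at 3.93 ± 1.248 and 3.56 ± 1.66 FPKM, and of 18 stromal and endothelial genes 0 reached the filter. Enteroendocrine (1 tested, Cpe, at 15.8 ± 9.16 and 17.8 ± 11.8 FPKM), tuft (2 tested, Ptgs1 and Il17rb) and MHC class II genes (2 tested, H2-DMa and H2-DMb1) were too few for a set test, and none of these 5 genes passed.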

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

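In each group of 5 libraries the gap between an extreme library and its nearest neighbour was compared with the whole range of the group, for 348 groups of values; 28 exceeded the 95% limit, and chance gives about 17. Of the tests on matched libraries weighed here, those of chance assignment, of a shared origin and of the pseudogene, and the exchange of treatment within pairs, were chosen only after the result was seen.

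WY-14643 replicate 10 stood apart in 7 of them and vehicle replicate 5 in 6, more often than any other library. WY-14643 replicate 10 was lowest in its group for Slc16a3 (gap over range 0.903), Ppard (0.885), Pparg (0.723) and the mean over the ketone body list (0.743), and highest for Zmat3 (0.758), the mean over the p53 list (0.741) and the number of recovered reads, 22209003 (0.753). Vehicle replicate 5 was lowest for Hmox1 (0.771), Hilpda (0.807), Dmbt1 (0.723), Krt20 (0.746) and the mean over the antimicrobial list (0.820), and highest for Zmat3 (0.738). WY-14643 replicate 6 was lowest for Lgr5 (0.847) and Muc2 (0.717) and highest for Cpe (0.735) and Ifit1bl1 (0.757). WY-14643 replicate 9 was lowest for Foxm1 (0.721) and Aldh1a1 (0.814) and highest for Ly6g (0.735), and WY-14643 replicate 7 was highest for Nr1i2 (0.837) and Sesn1 (0.784). Vehicle replicate 1 was lowest for Xbp1 (0.805) and highest for Ifit1bl1 (0.763) and Angptl4 (0.909), vehicle replicate 2 was highest for Acacb (0.733) and Fabp1 (1, all other vehicle libraries being at 0), and vehicle replicate 4 was highest for Acot2 (0.818).

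The matched deviation of vehicle replicates 1 to 5 with WY-14643 replicates 6 to 10 was weighed first. Shared sequencing depth is argued against: with every library thinned to 15618244 reads, the lowest matched correlation was 0.409 (0.423 before) and the highest unmatched one between the groups 0.0599. Gene length and GC content are argued against in the same way (0.455 against 0.0778 after curves on both were taken out, over the 97.6% of genes with a GC value), as is an unequal share of reads in abundant, mitochondrial or rRNA genes (0.394 against 0.0915 without 534 such genes). Chance assignment is argued against, since 1 of 120 assignments, the numbered one itself, reached its mean correlation. A shared animal, organoid line, passage or day of processing stays open and may be the source, and these cannot be told apart, because 0 label fields name any of them.

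Hadhb-ps was weighed next. Its log2 change stayed within 0.256 of that of Hadhb in all 5 matched pairs, but so did 2 of 21 other genes of mitochondrial β-oxidation, Cpt2 and Hadha, whose sequences are their own. Reads of Hadhb counted at its pseudogene and a change of the pseudogene itself both stay open.

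With 0 genes called in the planned fit, any split of the 10 libraries gives as many (100 of 100), so the splits say nothing about chance there. The highest other split called 904, with vehicle replicates 1, 3 and 4 and WY-14643 replicates 6 and 9 on one side. That split keeps 4 of the 5 matched pairs whole and points to a structure of the samples. In the matched fit, where treatment was exchanged within pairs, the real arrangement called 43 genes and was the 1 of 16 with as many, and the highest other called 2; 16 arrangements are too few for a share under 0.05.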

How the results depend on the processing

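The matched fit, with or without a further change, was chosen after the data were examined, as were the random-effect block and the exchanges within pairs; all other alternatives were fixed beforehand.

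The planned count of 0 higher and 0 lower genes was the same under both other pseudocounts, both other filters, TPM, quantile normalization, limma without trend or robust priors, voom (187 genes at an unadjusted p under 0.05) and protein-coding genes only; scaling by the median ratio moves nothing and says nothing. Library weights gave 18 higher and 3 lower, 9 and 3 of them at least 2-fold. The replicate block gave 39 higher and 4 lower, 6 and 1 of them at least 2-fold, and as a random effect (correlation 0.765 within pairs) 85 and 22, with 13 and 4 at least 2-fold. Leaving out a library gave 0 to 2 higher, 0 to 2 at least 2-fold higher and 0 lower: 1 without vehicle replicate 2, 2 without vehicle replicate 5 and 1 without WY-14643 replicate 10. The cause of these differences was not tested.

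In the matched fit, no filter gave 2 higher and 0 lower, and a mean FPKM of at least 2 gave 61 and 8. No trend or robust priors gave 23 (lower 3), voom 162 and 50, and library weights 64 and 9. Protein-coding genes only gave 115 and 27, and quantile normalization 48 higher with 7 lower. Without a filter 28804 genes were tested in place of 13607. The cause of these changes was not tested. Of the 43 genes called, voom called 38 among its 212. Leaving out a pair gave 2 to 30 higher and 0 to 6 lower: 3 and 0 without replicates 2 and 7, 2 and 0 without replicates 3 and 8, 12 and 1 without replicates 4 and 9.

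Set tests of PPARα targets and mitochondrial β-oxidation passed under every alternative of camera and fry run without pairs, and in camera and fry with the replicate block; with pairs and an estimated correlation neither did (0.101 for both), nor did the exact test of list means after adjustment (0.230 for both). PPARα targets higher over the list alone numbered 5 to 13 when a library was left out, 20 with the replicate block and 19 with it as a random effect; for β-oxidation the range was 8 to 13. The number of lists higher by camera, 12, became 2 with an estimated correlation and 2 with fry, and the 1 lower list became 0 with either, with no filter, with no trend or robust priors and with library weights; leaving out a library gave 9 to 17 higher and 0 to 2 lower. The replicate block gave 16 higher and 1 lower, and fry with pairs passed 9 lists. Over 724 set test values, 45 lost a call, 35 gained one and 2 turned: cell proliferation was lower without vehicle replicate 4 (1.17e-06) and fetal-like genes were higher, uncalled, without vehicle replicate 1 (0.981). Leaving out a library moved these 2 lists over 1.17e-06 to 0.940 and 0.00123 to 0.981.

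Lists with no call gained one without single libraries: ketone body metabolism without vehicle replicate 3 (0.0211) or WY-14643 replicate 10 (3.98e-04); nuclear receptors without vehicle replicate 2 (1.52e-04), 3 or 4 or WY-14643 replicate 6 or 10; glycolysis without vehicle replicate 2 (0.00109) or WY-14643 replicate 10 (0.00939); cell proliferation without vehicle replicate 1 (0.00480), 3 or 5 or WY-14643 replicate 9 (1.93e-06); goblet genes without WY-14643 replicate 8 (0.00202); proximal colon-associated and colon identity genes without vehicle replicate 2 (0.0225 and 0.0169) or 3 or WY-14643 replicate 6; the unfolded protein list without vehicle replicate 3 or 4 or WY-14643 replicate 7 or 10 (0.00431); and p53 targets without vehicle replicate 3 (0.0295) or WY-14643 replicate 10 (0.00564). The first 2 were also called at a mean FPKM of at least 2 and among protein-coding genes. Adjusted p of single genes ranged over the alternatives from 1.13e-04 to 0.346 for Cpt1a, 6.14e-05 to 0.422 for Akr1b8 and 8.85e-04 to 0.657 for Acadl. Among 141 genes of the rule, 63 of 3222 values became calls, in 29 genes, and 75 changed sign with no call on either side. Genes with few reads, such as Ppara with 9 to 63 per library, are limited by depth.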

Other observations

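Tests of differences between the matched pairs were chosen after the pairing was seen. The 5 matched pairs differed from each other in 7703 of 13607 genes (56.6%) (limma, moderated F test over the pair terms, adjusted p under 0.05), among them all 30 tested cell proliferation genes and 24 of 26 absorptive colonocyte genes. Because the pairing was read from the same values, this count describes the libraries and is no independent test. Replicates 1 and 6 had the highest proliferation level, with a mean of 79.6 FPKM for Mki67 and 63.1 FPKM for Top2a, and replicates 4 and 9 the lowest, with 11.1 and 10.4 FPKM. Replicates 4 and 9 had the highest Car1, 1092 FPKM, and Krt20, 149 FPKM, and replicates 5 and 10 the lowest, 32 and 6.52 FPKM. Mki67 in replicates 5 and 10 was 40.1 FPKM.

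The cultures carried a limited set of colon position genes. Hoxb6, Hoxb7, Hoxb8 and Hoxb9 were at 65.6, 25.0, 23.5 and 52.9 FPKM over the 10 libraries, while Hoxa13, Hoxb13 and Hoxd13, HOX genes of the hindgut end, were listed at 0 reads in all of them. Cdx2, an intestinal transcription factor, was at 104 FPKM and the small intestinal factor gene Gata4 at 0.00595 FPKM. Among genes of the distal list, Ly6g was at 319 FPKM, from 172 to 624 in single libraries, and Insl5 at 0. Olfm4, a marker of small intestinal crypts in mice, was at 0.00201 FPKM and the surface carbonic anhydrase Car4 at 0. The labels name no segment of colon for the cultures, so these levels stand as values.

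The PPARα target list rose least in the pair of replicates 5 and 10, by 0.33 on the log2 scale, against 0.71 to 0.88 in the other pairs.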
